A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

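Transcripts were measured by 3′ end sequencing of polyadenylated RNA (QuantSeq libraries on an Illumina HiSeq instrument, per the labels' protocols) in 6 samples of BY4741 yeast: 2 of WT, 2 of a bud27 deletion and 2 of WT incubated overnight with rapamycin. The submitters' processing notes name FastQC, HISAT2, DESeq and DESeq2 and the genome build R64, without versions. The counting tool, the annotation, the strand setting, the treatment of reads that map to several places and any filters are not given in the sources used here.

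The authors deposited a table of CPM values with 7247 rows and a column for each of the 6 samples. In each column 100% of the values were whole multiples, within 0.01 reads, of a single step that is the value of 1 read, so the reads per row were recovered. The totals behind the values were 26899486 and 18153459 reads for WT, 3212848 and 5088194 for the deletion and 28774941 and 20841682 for rapamycin, while the reads in the listed rows came to 21837672 and 14091620, 2211779 and 3679151, and 22460409 and 16268139. A value at 0 allows up to 3 reads, which is 0.112 CPM in the deepest WT library and 0.934 CPM in the shallowest deletion library. Such floors and intervals cover counting error only. Of the rows, 925 are named as cryptic unstable transcripts (CUTs) and 847 as stable unannotated transcripts (SUTs), and 5475 hold genes, 297 of which join several features. Of 5780 feature names in the gene rows, 5536 matched the reference annotation of build R64, and 5426 of its 6021 protein-coding genes are named in a row. CUT and SUT rows were kept out of the gene comparisons because 30 of the 482 with over 300 reads in all held the reads of a gene row, within 0.1 log2 units in every library.

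The comparisons, the tests, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The test chosen then was a count test with edgeR, or limma on log2(value + 1) should the values be normalized. As the unit is CPM, limma 3.58.1 (R 4.3.3) with an abundance trend was fitted to log2(scaled CPM + 1), with the 3 groups in 1 model and 3 residual degrees of freedom. CPM were first rescaled by TMM factors (edgeR 4.0.16), the normalization fixed beforehand, with factors of 0.767 and 0.805 for WT, 1.12 and 1.01 for the deletion and 1.19 and 1.20 for rapamycin. The wording of the fallback did not mention this rescaling, so the deposited scale was added as an alternative. It raises the median log2 fold change of all rows by 0.40 in the deletion and 0.55 after rapamycin and lowers that of the deletion against rapamycin by 0.16, and no spike-in is used here that would set the absolute level. Rows passed edgeR's expression filter by group (minimum count 10), which kept 5279 rows, 281 of them joined. Adjusted p-values follow Benjamini and Hochberg, and 0.05 was the threshold.

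The 30 lists of genes fixed by name were compared with all other genes by camera with a preset correlation of 0.01 and with an estimated one, and by fry, which asks whether a list moves on balance in 1 direction and does not compare it with other genes. p-values were adjusted over the 30 lists in each comparison. By their names RPP1 entered the cytosolic ribosomal protein list, MRP8 the mitochondrial one and MLP1 the cell wall list, although they are not of these kinds. The lists were kept as fixed, and tests without these genes, added after seeing the data, kept each call or lack of one by camera. With an estimated correlation no list was called, and the smallest adjusted p was 0.30 for the deletion, 0.15 for rapamycin and 0.20 for the difference. That version of camera rests on the 3 residual degrees of freedom, so the lost calls need not come from correlation between genes. After rapamycin the autophagy list had an estimated correlation of -0.01, below the preset 0.01, yet its camera adjusted p went from 2e-06 to 0.15. That of RNA polymerase I, with a correlation of -0.04, went from 0.00077 to 0.15. Of the lists not called by camera, fry calls several, and in all it calls 16, 27 and 26. For each list, 10000 lists were drawn from other rows, each member replaced by 1 of the 20 rows nearest in WT abundance outside the ribosomal protein, translation factor and glycolysis lists. They are called matched lists or lists of equal WT abundance below. No limit was set on the distance, so rows drawn for the most abundant members may be less abundant than these members. Members were drawn independently, so the percentiles ignore correlation within a list and may be too extreme. Genes were named by a rule: BUD27, the 6 largest rises and 6 largest falls among called genes with a mean of at least 20 CPM over the 6 libraries, a standard name and both libraries on the same side of both WT libraries, and up to 2 leading members of each list. The leading members of a fixed list are its called genes with the largest absolute log2 fold change and a mean of at least 20 CPM. Members below that mean, and joined rows, are passed over, also where a list is said to be led or a member to change most. For the deletion against rapamycin the 5 largest in each direction were taken. Some genes that meet this rule are not reported here. Genes deleted in BY4741 and rows joining several genes are not named by this rule, and genes with a copy of at least 90% identity over 0.5 of their length (blastn 2.17.0) are called uncertain.

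On simulated reads for 5224 genes the test for the deletion called 87.8%, 64.0%, 83.7% and 100% of genes changed by a log2 fold of -2, -1, 1 and 2, and 0.24% of unchanged genes. The test for rapamycin called 91.8%, 70.0%, 78.0% and 92.0%, and 0.10% of unchanged genes. In these simulations only 49 or 50 genes were changed at each fold, about as many up as down. In the data far more rows were called, and their split depends on the scaling. The simulated rates, that of unchanged genes included, may therefore not hold for the data. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 26.8 in WT, 17.8 in the deletion and 41.2 with rapamycin, so none was counted as a duplicate. The alternatives chosen beforehand were other size factors, scaling without ribosomal genes, other filters, pseudocounts and thresholds, DESeq2 1.42.0, only the 2 groups compared, the replicate number as a block, and each library left out in turn. Added after seeing the data were the deposited scale, edgeR and voom on the recovered reads, all rows, no joined rows, and all libraries thinned to the shallowest. On the recovered reads edgeR's quasi-likelihood test called 2447 genes in the deletion, 2658 after rapamycin and 2912 between them. Figures were drawn with matplotlib 3.10.9.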

Results

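Transcript levels were measured in 6 samples of the budding yeast Saccharomyces cerevisiae BY4741, a haploid laboratory strain of mating type a. There were 2 samples of WT, 2 of a bud27 deletion and 2 of WT treated overnight with rapamycin at 50 ng/ml, all grown in rich glucose medium at 30 °C and harvested near an optical density of 0.8. BUD27 encodes a prefoldin-like protein, and rapamycin inhibits the TOR complex 1 kinase. The libraries were made with a kit that sequences a short stretch near the 3′ end of each polyadenylated transcript, so the values are reads per transcript and do not grow with its length. The deposited values were CPM, read counts scaled to a common library total, and the reads behind them could be recovered. The WT libraries rested on 26899486 and 18153459 reads, the rapamycin libraries on 28774941 and 20841682, and the deletion libraries on only 3212848 and 5088194. Reads outside the listed rows made up 18.8% and 22.4% of these totals in WT, 21.9% and 21.9% after rapamycin, and 31.2% and 27.7% in the deletion. The 100 most abundant gene rows held 58.1% and 56.5% of the gene reads in WT, against 43.9% and 47.9% in the deletion and 44.8% and 44.5% after rapamycin. Nothing in the labels says that samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. Fold changes are on the log2(scaled CPM + 1) scale, which understates the change of rare transcripts, and a gene passed the test at a limma adjusted p below 0.05 over the 5279 gene rows tested.

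BUD27 itself, on chromosome VI at 90986 to 93376 on the plus strand of the R64 reference, checked the labels first. It had 268 and 246 reads in WT, 6 and 9 in the deletion, and 326 and 234 after rapamycin. Its level fell by 2.54 on the log2 scale in the deletion (SE 0.18, adjusted p = 4.9e-05), from 14.9 ± 2.72 to 1.71 ± 0.0626 scaled CPM (SD, n = 2). The labels do not say which part of the gene was removed, and reads from the 3′ end that lie outside the removed part would check nothing. The neighbour FRS2, a subunit of phenylalanyl-tRNA synthetase that runs towards BUD27 from 95010 to 93499 on the minus strand, also fell, by 2.17 (SE 0.25, adjusted p = 0.00044), and reads of converging genes cannot be told apart where the counting did not use strand. EPL1, on the other side, had a log2 fold change of -0.07 (SE 0.19, adjusted p = 0.77). After rapamycin BUD27 had a log2 fold change of -0.60 (SE 0.18, adjusted p = 0.03). That call was lost without WT replicate 2 (adjusted p = 0.17), without rapamycin replicate 1 (0.16) or replicate 2 (0.17), and on the deposited CPM scale (log2 fold change -0.04, adjusted p = 0.87).

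The first comparison asked which transcripts differ between the bud27 deletion samples and WT. The deletion samples also had less FRS2 and few TRP1 reads (5 and 8, against 738 and 626 in WT). The differences that follow therefore cannot be assigned to the loss of Bud27 alone. The largest rise in the deletion among the genes named was that of ARG1, and the largest fall that of TIR1. ARG1, the argininosuccinate synthetase gene on chromosome XV at 219211 to 220473, went from 17.5 ± 3.69 to 1760 ± 236 scaled CPM (SD, n = 2), a log2 fold change of 6.58 (SE 0.17, adjusted p = 4.3e-07). TIR1, a cell wall mannoprotein gene on chromosome V at 175248 to 176012, went from 178 ± 17.0 to 1.57 ± 0.259 scaled CPM, a log2 fold change of -6.12 (SE 0.14, adjusted p = 4.3e-07). It had 3924 and 2428 reads in WT but 5 and 9 in the deletion. The model gives each gene 1 spread for all libraries, shallow and deep, so an SE may understate counting error at so few reads.

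Among the other genes with the largest rises were SNO1 of vitamin B6 metabolism at 5.62, with 4 and 0 reads in WT and 181 and 283 in the deletion, ARO5 at 4.63, the lysine gene LYS1 at 4.58 and the arginine gene ARG4 at 4.57. Among the largest falls were the siderophore-binding cell wall proteins FIT3 at -4.88 and FIT2 at -4.59, the hexose transporter HXT4 at -4.58, ANB1 at -4.04 and the tryptophan gene TRP1 at -4.02. The standard errors of these 9 fold changes ran from 0.12 for LYS1 to 0.28 for ANB1. HXT4 had 7 and 12 reads in the deletion, so its SE of 0.18 may be too small. That both deletion libraries lay on the same side of both WT libraries was a condition for naming these genes. ANB1, a low-oxygen form of translation factor eIF5A, had 1 read in the deletion against 639 in WT. Its read ratio was 158-fold lower after scaling, with an exact 95% counting interval of 28.3 to 6270, and its near-identical copy HYP2 makes the assignment of its reads uncertain.

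Of the genes activated by Gcn4, the transcription factor of the amino acid starvation response, 48 of 61 rose and 2 fell (48 and 3 adjusted over the list alone), with a median log2 fold change of 1.76. The list stood above the other genes in the camera test (adjusted p = 6.1e-18, and adjusted p = 0.30 with an estimated correlation). Oxidative phosphorylation had 19 higher and 3 lower of 40 (20 and 3 adjusted over the list alone), a median of 0.56 and camera adjusted p = 5.5e-06, with adjusted p = 0.50 with an estimated correlation. Among its members with a mean of at least 20 CPM, QCR7 of respiratory complex III at 2.44 (SE 0.14) and the cytochrome c gene CYC7 at 2.04 (SE 0.23) changed most. In the tricarboxylic acid cycle and retrograde list 14 rose and 3 fell of 29 (15 and 3 adjusted over the list alone), with IDP1, a mitochondrial isocitrate dehydrogenase, at 2.21 (SE 0.14). Its camera adjusted p was 0.0039, and adjusted p = 0.40 with an estimated correlation. The phosphate regulon had 7 higher and none lower of 14, the same count adjusted over the list alone (camera adjusted p = 0.0068, and adjusted p = 0.31 with an estimated correlation). Its leading members were the phosphate transporter PHO84 at 4.21 (SE 0.13) and SPL2 at 3.97 (SE 0.23). Without deletion replicate 2 the phosphate list had a camera adjusted p of 0.058.

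Glycolysis and fermentation had the lowest median of the 30 lists, at -1.40, with 18 of 21 rows lower and none higher (19 lower adjusted over the list alone; camera adjusted p = 8.1e-08, and adjusted p = 0.30 with an estimated correlation). HXT4 led it, followed by PGK1, the phosphoglycerate kinase gene, at -3.49 (SE 0.39). Of the cell wall list 21 of 31 rows fell and 1 rose (23 and 2 adjusted over the list alone), with a median of -0.96 and camera adjusted p = 3.2e-06. Without MLP1, which is not a cell wall gene, 21 of 30 fell and none rose. Of the iron regulon 16 of 23 fell and 2 rose, the same counts adjusted over the list alone, with a median of -0.72 and camera adjusted p = 0.00038. For both lists the adjusted p = 0.30 with an estimated correlation. PIR1, a cell wall glycoprotein gene, fell by 3.49 (SE 0.30). Translation factors had 25 of 36 lower and none higher, the same counts adjusted over the list alone, a median of -0.80 and camera adjusted p = 2e-05 (adjusted p = 0.50 with an estimated correlation). On the deposited CPM scale their median was -0.36. They included the elongation factor YEF3 at -2.04 (SE 0.22) and TIF2 at -2.24 (SE 0.23), whose value is uncertain because its reads can be split with the near-identical TIF1.

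In the cytosolic ribosomal protein list, whose name pattern also took in the RNase P subunit RPP1, 71 of 137 rows were lower and 9 higher (76 and 10 adjusted over the list alone), with a median of -0.56 and camera adjusted p = 3.5e-07. Without RPP1 71 of 136 were lower. On the deposited CPM scale the median of the list was -0.13, against 0.38 for all rows. Ribosome biogenesis genes had 48 lower and 12 higher of 133, the same counts adjusted over the list alone, with a median of -0.24 that turned to 0.19 on the deposited CPM scale, and camera adjusted p = 0.0041. Both lists had adjusted p = 0.50 with an estimated correlation. The call for ribosome biogenesis was lost without deletion replicate 2 (adjusted p = 0.078) and on the deposited scale (0.079). Its leading members were the GTPase NOG1 at -3.19 (SE 0.17) and the nucleolar protein NSR1 at -2.65 (SE 0.15). Of the ribosomal protein genes, RPL41A at -3.14 (SE 0.32) and RPL2B at -2.36 (SE 0.25) changed most, both uncertain because of near-identical copies. Abundance moved with these groups: in the 528 rows most abundant in WT the median log2 fold change was -0.65 in the deletion and -0.76 after rapamycin. Lists drawn from the other rows nearest in WT abundance had a median of -0.91 beside the ribosomal proteins, -0.90 beside glycolysis and -0.55 beside the translation factors in the deletion. The ribosomal proteins thus lay above their matched lists (percentile 100) and the other lists below (0.69 and 4.9). Of the 10 lists called in the deletion, translation factors and ribosome biogenesis, at -0.24 against -0.13 (percentile 5.59), lay in the middle 95% of their matched lists.

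The remaining lists were not called by camera in the deletion (adjusted p from 0.18 for histones to 0.88 for nitrogen catabolite repression). Among them, ergosterol synthesis at 0.21 against -0.25 (percentile 99.9), the proteasome at 0.02 against -0.36 (99.5) and the Msn2/4 stress list at -0.19 against 0.04 (2.1) lay outside the middle 95% of lists of equal WT abundance. The median of the last was 0.23 on the deposited scale. RNA polymerase I had 1 higher and 5 lower of 15, RNA polymerase II 3 and 1 of 7, RNA polymerase III 6 and 5 of 20, their shared subunits 0 and 3 of 7, and the prefoldin, CCT chaperonin and R2TP list 4 and 5 of 18. Nitrogen catabolite repression had 10 and 8 of 32, with a median of -0.10 that became 0.00 when 2 members without reads in a group were set to their bound and was 0.32 on the deposited CPM scale. For this list the camera direction was up although the median and the mean (-0.05) lay below 0, and for the proteasome the median was 0.02 and the mean -0.03. The Msn2/4 stress list had 10 and 14 of 45, led by PHM8 at 2.49 (SE 0.20) and TMA10 at -2.47 (SE 0.41), and the Hsf1 chaperones 4 and 11 of 27, led by HSP78 at 1.77 (SE 0.14) and the uncertain SSA2 at -2.53 (SE 0.29). Methionine and sulfate assimilation had 6 and 6 of 20, mitochondrial ribosomal proteins 14 and 10 of 65, gluconeogenesis with fat oxidation 1 and 5 of 22, autophagy 8 and 4 of 33, the proteasome 5 and 7 of 37, ergosterol synthesis 11 and 7 of 27, and cytosolic tRNA synthetases 5 and 8 of 19. Histones had 0 and 5 of 10, and their list was called only without deletion replicate 2 (camera adjusted p = 0.025). Mating and sporulation markers gave 0 and 2 of 6 a-specific genes, 0 and 1 of 2 alpha-specific genes, 1 and 3 of 11 sporulation genes and 1 and 5 of 12 pheromone response genes. Adjusted over the list alone, these counts moved by at most 2 genes in either direction.

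**Figure D1:**
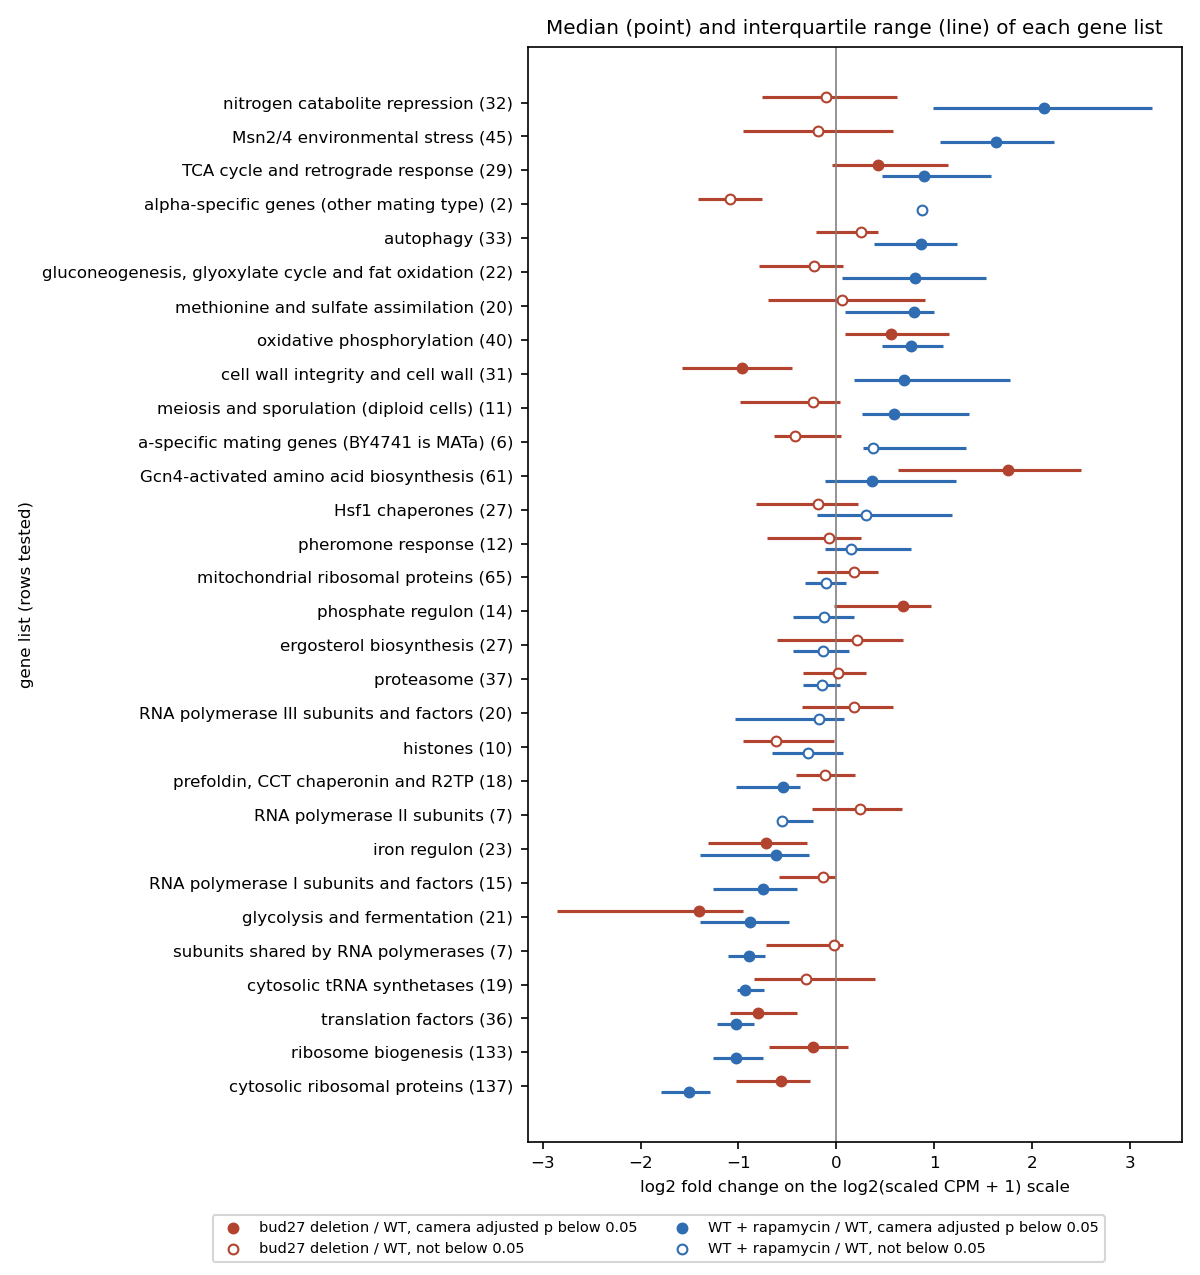
Median log2 fold change of each gene list (points) and its interquartile range (lines), for the bud27 deletion against WT (red) and rapamycin-treated WT against WT (blue), with the rows tested in brackets. Filled points have a camera adjusted p below 0.05, a call that no list kept with an estimated correlation. The Gcn4 list lies at 1.76 in the deletion, and nitrogen catabolite repression at 2.12 after rapamycin.

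In this comparison 2492 of 5279 rows passed the test, 1147 higher and 1345 lower in the deletion, and 975 of them differed at least by a log2 fold change of 1 (360 higher, 615 lower). The direction of the bulk depends on the scaling: on the deposited CPM scale 2245 rows were higher and 704 lower, since the median of all rows moves from -0.02 to 0.38 there. The count was 1498 without WT replicate 1 and 1431 without WT replicate 2.

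The second comparison asked what rapamycin, given to block the TOR pathway, changed in WT cells. HSP26, a small heat shock protein gene on chromosome II at 382030 to 382674, went from 12.9 ± 2.58 to 1350 ± 122 scaled CPM (SD, n = 2), a log2 fold change of 6.62 (SE 0.22, adjusted p = 1.7e-06). MEP2, an ammonium transporter gene, rose from 5.21 ± 1.06 to 364 ± 10.2 scaled CPM, a log2 fold change of 5.89 (SE 0.17, adjusted p = 1.6e-06). DPI8 at 5.84, the NADP-dependent glutamate dehydrogenase GDH3 at 5.54, the stress gene DDR2 at 5.27 and the allantoin degradation gene DAL3 at 5.13 followed.

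The largest falls were smaller than the largest rises. HXT1, a low-affinity glucose transporter, went from 318 ± 47.2 to 42.3 ± 0.158 scaled CPM (SD, n = 2), a log2 fold change of -2.87 (SE 0.15, adjusted p = 1e-05). It was followed by FIT3 at -2.73, the ribosomal protein gene RPL9A at -2.68, the acid phosphatase PHO3 at -2.64, RPS14B at -2.62 and the acetaldehyde dehydrogenase ALD6 at -2.46, with standard errors of 0.14 to 0.18. RPL9A is uncertain because of its near-identical copy RPL9B, and RPS14B shares a long stretch with RPS14A. The rule that named these genes required both rapamycin libraries to lie on the same side of both WT libraries.

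The cytosolic ribosomal protein list had 129 of 137 rows lower and 1 higher after rapamycin (128 of 136 lower without RPP1, and 132 and 1 adjusted over the list alone), with a median of -1.51 and camera adjusted p = 1.2e-33, against a median of -0.59 in lists of equal WT abundance. Ribosome biogenesis had 110 of 133 lower and none higher (116 adjusted over the list alone), with a median of -1.02 and camera adjusted p = 4.3e-26, against -0.10 in lists of equal abundance, and was led by FPR4 at -2.05 (SE 0.18) and GAR1 at -1.85 (SE 0.16). With an estimated correlation the adjusted p = 0.16 for the first list and adjusted p = 0.15 for the second. Translation factors had 33 of 36 lower and none higher (34 adjusted over the list alone; median -1.02, camera adjusted p = 1.8e-11, and adjusted p = 0.18 with an estimated correlation), and tRNA synthetases 18 of 19 lower and none higher, the same counts adjusted over the list alone (median -0.93, camera adjusted p = 4.1e-07, and adjusted p = 0.15 with an estimated correlation). Among the synthetases GLN4 changed most, at -1.65 (SE 0.15). All 7 subunits shared by RNA polymerases fell (median -0.89, camera adjusted p = 0.00052), led by RPB8 at -1.25 (SE 0.12). RNA polymerase I had 8 of 15 lower and none higher (median -0.75, camera adjusted p = 0.00077), led by RPA135 at -1.58 (SE 0.13), which is its second largest subunit. The shared subunits lay at percentile 8.36 of lists of equal WT abundance (matched median -0.36), inside their middle 95%. Both polymerase lists kept these counts adjusted over the list alone and had adjusted p = 0.15 with an estimated correlation.

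The prefoldin, CCT chaperonin and R2TP list had 10 lower and 1 higher of 18, the same counts adjusted over the list alone, with a median of -0.54 that turned to 0.06 on the deposited CPM scale. Its camera adjusted p was 0.00028, and adjusted p = 0.17 with an estimated correlation, and CCT7 of the chaperonin stood at -1.33 (SE 0.12). The iron regulon had 13 of 23 lower and none higher, the same counts adjusted over the list alone (median -0.62, camera adjusted p = 3.9e-05, and adjusted p = 0.15 with an estimated correlation), with the ferroxidase FET3 at -2.29 (SE 0.15) after FIT3. Glycolysis had 13 lower and 3 higher of 21 (15 and 4 adjusted over the list alone; median -0.88, camera adjusted p = 0.0034, and adjusted p = 0.28 with an estimated correlation). It lay inside the middle 95% of lists of equal WT abundance (matched median -0.51, percentile 3.3). TDH1, 1 of the genes that rose, stood at 2.87 (SE 0.22) and is uncertain because of its near-identical copy TDH2.

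Of the genes under nitrogen catabolite repression, which are switched on when good nitrogen sources run out, 27 of 32 rose and 1 fell, the same counts adjusted over the list alone, with a median of 2.12 and camera adjusted p = 2.8e-12 (adjusted p = 0.15 with an estimated correlation). Of the Msn2/4 stress genes 35 of 45 rose and none fell (37 and 1 adjusted over the list alone), with a median of 1.63, camera adjusted p = 2.3e-12 and adjusted p = 0.19 with an estimated correlation. Autophagy genes had 24 higher and 1 lower of 33, the same counts adjusted over the list alone (median 0.87, camera adjusted p = 2e-06), led by ATG8 at 2.49 (SE 0.17) and ATG33 at 2.22 (SE 0.20). The tricarboxylic acid cycle and retrograde list had 21 higher and 1 lower of 29, the same counts adjusted over the list alone (median 0.90, camera adjusted p = 4.8e-06), with the peroxisomal citrate synthase CIT2 at 3.96 (SE 0.23). Both had adjusted p = 0.15 with an estimated correlation. Oxidative phosphorylation had 28 higher and 2 lower of 40 (29 and 3 adjusted over the list alone), with a median of 0.76 and camera adjusted p = 2e-06. Among its members with a mean of at least 20 CPM, COX5B at 3.45 (SE 0.13) and SDH2 at 2.55 (SE 0.24) changed most. Gcn4-activated genes had 26 and 8 of 61 (27 and 9 adjusted over the list alone), with a median of 0.37 and camera adjusted p = 0.003. ARG1 stood at 4.24 (SE 0.17) and ARG3 at 3.29 (SE 0.15). Gluconeogenesis with fat oxidation had 11 and 1 of 22 (12 and 1 adjusted over the list alone), with a median of 0.80 and camera adjusted p = 0.003. Each of these 3 had adjusted p = 0.28 with an estimated correlation, and the gluconeogenesis call was lost on the deposited scale (0.099).

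Cell wall genes had 17 higher and 3 lower of 31 (18 and 3 adjusted over the list alone), with a median of 0.69, camera adjusted p = 0.00035 and adjusted p = 0.19 with an estimated correlation. TIR1, at 2.94 (SE 0.14), and the glucan synthase subunit GSC2, at 2.74 (SE 0.17), led them. Methionine and sulfate assimilation had 11 higher and 3 lower of 20 (12 and 3 adjusted over the list alone; camera adjusted p = 0.038, and adjusted p = 0.28 with an estimated correlation), and this call was lost without WT replicate 1 (0.082), with a stricter read filter (0.062) and on the deposited scale (0.14). Sporulation genes had 5 higher and none lower of 11, the same counts adjusted over the list alone (camera adjusted p = 0.029, and adjusted p = 0.19 with an estimated correlation), and lost the call without rapamycin replicate 2 (0.051), with the stricter filter (0.063) and on the deposited scale (0.17). Their median of 0.59 stood beside 0.53 in lists of equal WT abundance (percentile 66.3). Of the 19 lists called after rapamycin only these, glycolysis and the shared polymerase subunits lay in the middle 95% of such lists. The other lists did not pass camera (adjusted p from 0.052 to 0.36), although Hsf1 chaperones at 0.30 against -0.16 (percentile 99.9) and a-specific genes at 0.38 against -0.25 (98.4) lay outside the middle 95% of lists of equal WT abundance. They were RNA polymerase II with 0 higher and 5 lower of 7, RNA polymerase III with 2 and 9 of 20, Hsf1 chaperones with 12 and 6 of 27, mitochondrial ribosomal proteins with 5 and 6 of 65, the proteasome with 2 and 7 of 37, the phosphate regulon with 2 and 4 of 14, ergosterol synthesis with 3 and 8 of 27, histones with 0 and 3 of 10, a-specific genes with 3 and 0 of 6, alpha-specific genes with 2 and 0 of 2 and pheromone response with 5 and 2 of 12. Adjusted over the list alone, these counts moved by at most 3 genes in either direction. The RNA polymerase III list was called as lower without WT replicate 1 (adjusted p = 0.050), without rapamycin replicate 1 (0.023) and on the deposited scale (0.037), where its median was 0.35 against 0.60 for all rows. The a-specific list was called as higher without deletion replicate 1 or 2 (0.035 each), without rapamycin replicate 1 (0.044), with no low-count filter (0.046), without joined rows (0.048), with thinned libraries (0.034) and on the deposited scale (0.037).

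**Figure D2:**
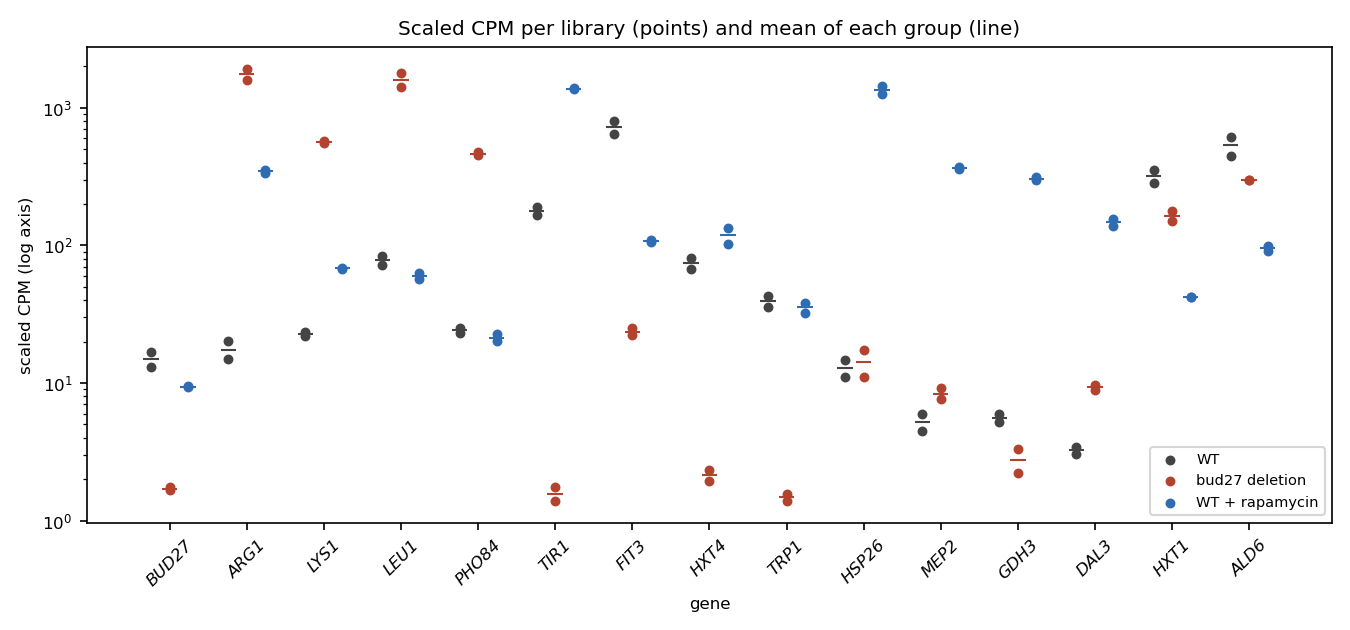
Scaled CPM on a log axis of 15 named genes in each library (points), with the mean of the 2 libraries of each group (short lines), for WT (grey), the bud27 deletion (red) and WT with rapamycin (blue). TIR1 lies at 1.57 in the deletion and 1370 after rapamycin against 178 in WT.

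After rapamycin 2421 rows passed the test, 1286 higher and 1135 lower, and 1037 of them differed at least by a log2 fold change of 1 (568 higher, 469 lower). On the deposited CPM scale 2886 rows were higher and 432 lower, since the median of all rows moves from 0.05 to 0.60 there. The count was 1605 without WT replicate 1, 1611 without WT replicate 2 and 1585 without rapamycin replicate 1.

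The deletion and rapamycin were then tested against each other, which asks directly where their effects differ. Among the genes furthest above the rapamycin samples in the deletion were the leucine gene LEU1 at 4.70 (SE 0.16), SPL2 at 4.43 (SE 0.23), PHO84 at 4.38 (SE 0.13) and the branched-chain aminotransferase BAT1 at 3.44 (SE 0.13). Those furthest below were TIR1 at -9.07 (SE 0.14), ANB1 at -7.13 (SE 0.28), HSP26 at -6.50 (SE 0.22), GDH3 at -6.36 (SE 0.18) and the GABA permease UGA4 at -5.70 (SE 0.19). In the deletion TIR1 had 5 and 9 reads, GDH3 8 and 17 and UGA4 5 and 10, so their SEs may be too small. ANB1 had 1 read in the deletion against 9284 after rapamycin, a ratio 1370-fold lower after scaling with an exact 95% counting interval of 245 to 54000. Among the rows tested 2908 passed, 1354 higher and 1554 lower in the deletion, and on the deposited CPM scale the split was 938 higher and 1829 lower, with the median of all rows moving from -0.01 to -0.17.

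The ribosomal protein list was higher in the deletion than after rapamycin in 95 of 137 rows and lower in 3 (94 of 136 higher without RPP1, and 99 and 3 adjusted over the list alone; median 0.90, camera adjusted p = 2.3e-14, and adjusted p = 0.24 with an estimated correlation). Ribosome biogenesis was higher in 87 of 133 and lower in 5 (90 and 6 adjusted over the list alone; median 0.67, camera adjusted p = 2.7e-11), and Gcn4-activated genes were higher in 45 of 61 and lower in 4 (46 and 5 adjusted over the list alone; median 1.33, camera adjusted p = 1.8e-11). Both had adjusted p = 0.20 with an estimated correlation. Nitrogen catabolite repression was lower in 27 of 32 rows and higher in none (28 and 1 adjusted over the list alone, median -2.30, camera adjusted p = 1.2e-10). The cell wall list was lower in 26 of 31 and higher in 2, the same counts adjusted over the list alone (median -1.46, camera adjusted p = 4.5e-09). Without MLP1 26 of 30 were lower and 1 higher. The nitrogen and cell wall lists also had adjusted p = 0.20 with an estimated correlation. The Msn2/4 stress list was lower in 37 of 45 and higher in 1 (38 and 1 adjusted over the list alone; median -1.69, camera adjusted p = 1.8e-11, and adjusted p = 0.23 with an estimated correlation). Oxidative phosphorylation was split, with 9 higher and 13 lower of 40 (camera adjusted p = 0.99), and so was the iron regulon, with 5 and 7 of 23 (0.75). In total 22 of the 30 lists were called, 12 higher and 10 lower, and none with an estimated correlation, where the smallest adjusted p = 0.20. Of these, the calls of ergosterol synthesis (adjusted p = 0.072), translation factors (0.21) and the alpha-specific genes (0.075) were lost without deletion replicate 2, those of mitochondrial ribosomal proteins and the alpha-specific genes without deletion replicate 1 (0.055 each), and that of translation factors without rapamycin replicate 1 (0.091). The translation factor call was also lost without joined rows (0.10), with the stricter read filter (0.051) and under fry (0.07). The alpha-specific call was lost with no low-count filter (0.51), with thinned libraries (0.069) and on the deposited scale (0.065). The mitochondrial ribosomal protein call was lost on the deposited scale too (0.065). The RNA polymerase II list, not called with all libraries, was called as higher without deletion replicate 2 (0.035) or rapamycin replicate 1 (0.042). It was also called with other size factors or scaling without ribosomal genes (0.049 each), with no low-count filter (0.048), with the replicate block (0.044) and with thinned libraries (0.038). Of the 22 lists, 7 lay in the middle 95% of lists of equal WT abundance: shared polymerase subunits, mitochondrial ribosomal proteins, glycolysis, the phosphate regulon, a-specific, alpha-specific and sporulation genes.

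The title of the series sets both conditions side by side against WT, so the overlap of their calls was counted. There were 438 genes higher in both and 528 lower in both, or 966 with the same sign, and independent lists of the same sizes would share 279.4 and 289.2. Another 104 were higher in the deletion and lower after rapamycin, and 229 the reverse. Across genes, which are not independent replicates, the log2 fold changes had Pearson r = 0.29 and Spearman rho = 0.31. Both comparisons share the WT libraries: with no effect at all, 50 simulations against the same controls gave a mean r of 0.42 and at most 1 gene called in both with the same sign. With no effect hardly any gene is called, so that count cannot show how many of the 966 come from the shared WT libraries. The covariance was 0.23 against a simulated 0.02, a difference of 0.21. With a different WT library for each comparison, r was 0.28 or 0.24, and the covariance 0.23 or 0.20. The controls cannot be split into parts of at least 2 libraries, so part of the excess over independent lists may come from sharing them. Without WT replicate 1 there were 514 genes called with the same sign, without WT replicate 2 492 and without rapamycin replicate 1 599, and on the deposited CPM scale 1713.

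**Figure D3:**
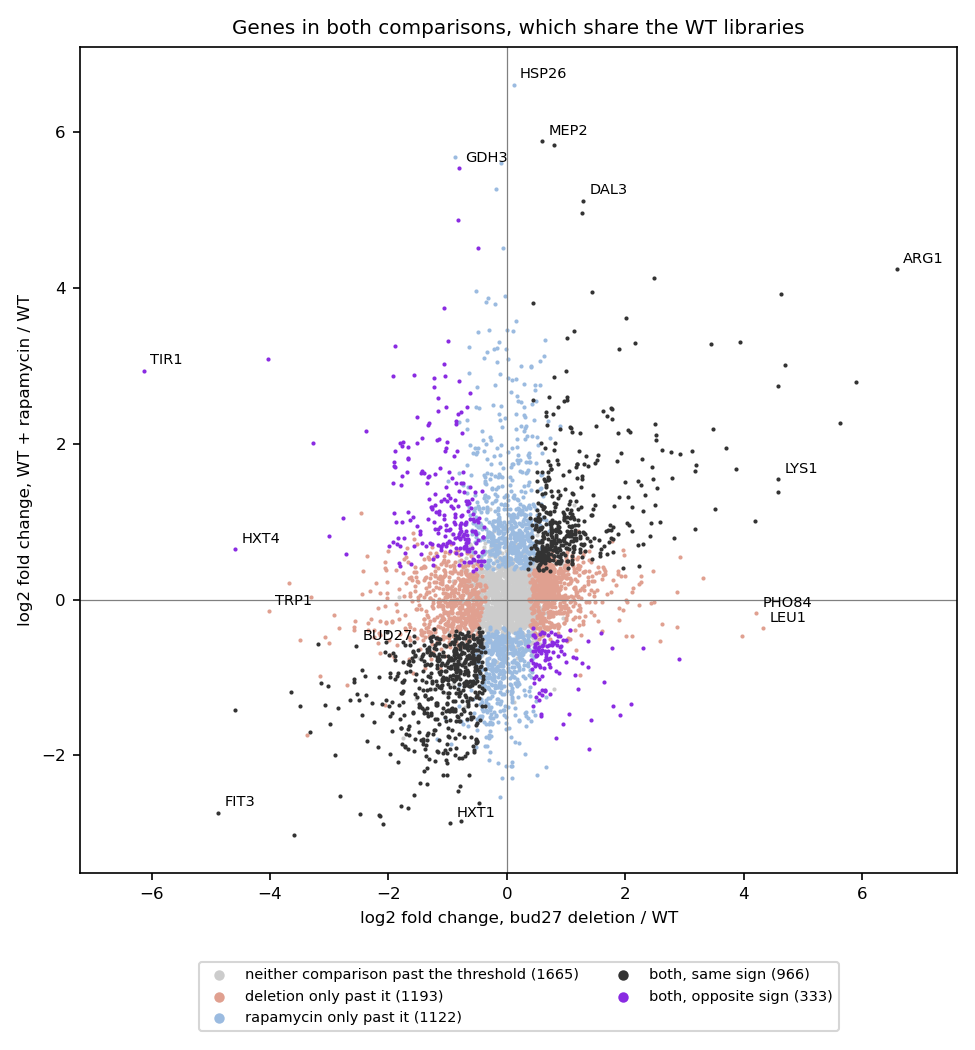
Log2 fold change of the bud27 deletion against WT (x axis) and of rapamycin-treated WT against WT (y axis) for the 5279 rows tested, coloured by which comparison passed the test. The 966 rows called in both with the same sign lie in the lower left and upper right, and TIR1 lies at -6.12 and 2.94.

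**Figure D4:**
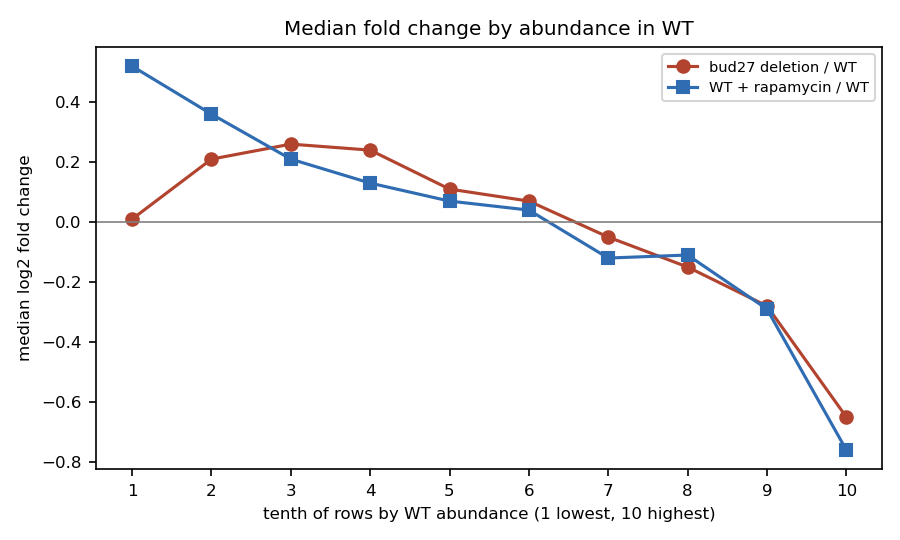
Median log2 fold change (y axis) of rows ordered by WT abundance and divided into 10 groups of equal size (x axis, lowest to highest), for the bud27 deletion (red circles) and rapamycin (blue squares). The most abundant group lies at -0.65 and -0.76, and the lowest at 0.01 and 0.52.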

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

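All tests in this part were chosen after the data were seen. CUTs and SUTs, short-lived and more stable transcripts from outside annotated genes, entered none of the gene comparisons, and some of their rows lay above WT. Tested as a family of their own with limma, with the scaling taken from the gene rows and without the 30 rows that hold the reads of a gene, 56 of 580 CUT rows were higher and 151 lower in the bud27 deletion, and 61 of 662 SUT rows were higher and 184 lower. After rapamycin 40 CUT rows were higher and 162 lower, while 197 SUT rows were higher and 54 lower. The median log2 fold changes were -0.32 for CUTs and -0.30 for SUTs in the deletion, and -0.42 and 0.33 after rapamycin. Tested against each other, the deletion had 142 CUT rows higher and 103 lower than rapamycin (median 0.10), and 52 SUT rows higher and 311 lower (median -0.58). On the deposited CPM scale the counts in the deletion were 72 higher and 83 lower for CUTs and 84 and 98 for SUTs, with medians of -0.08 and -0.03, and after rapamycin 91 and 86 for CUTs and 327 and 26 for SUTs, with medians of -0.11 and 0.72. For the deletion against rapamycin they were 129 and 121 for CUTs and 49 and 343 for SUTs there, with medians of 0.03 and -0.70. Many such transcripts overlap genes or run antisense to them, and the strand setting of the counting is not given in the sources used here. No explanation of these counts was tested.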

How the results depend on the processing

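Among the tests here, the deposited scale, edgeR and voom on recovered reads, all rows, no joined rows and thinning were chosen after the data were seen. No called gene was called in the opposite direction under any of the alternatives run, the fold change of no named gene changed sign, and the camera direction of no called list reversed. On the deposited scale 31 genes called in the deletion and 202 called after rapamycin had a fold change of the opposite sign, none of them called there. Of the 30 lists fixed beforehand, the medians of 2 called ones turned there as well, ribosome biogenesis in the deletion (-0.24 to 0.19) and the prefoldin, CCT chaperonin and R2TP list after rapamycin (-0.54 to 0.06). For the named genes 50 results lost the call and 2590 kept their side of the threshold, and most losses came with a WT library left out (16 and 14) or on the deposited scale (12). For the lists 1329 results kept their side, 74 lost the call, 51 of them with an estimated correlation, and 37 gained it, 19 of them under fry. Leaving out each library in turn, the number of genes called ranged from 1431 to 3034 in the deletion, 1585 to 3064 after rapamycin and 2034 to 3268 between them, the genes called in both with the same sign from 492 to 1310, and the log2 fold change of BUD27 from -2.74 to -2.39. A lone sample is then assumed to vary like the other groups. On the deposited scale 1713 genes were called in both with the same sign, and the cause was not tested. An adjusted p of 0.01 left 1507, 1584 and 491 genes for the deletion, rapamycin and both, and a log2 fold change of 1 left 975, 1037, 1304 between the conditions and 257, fewer by construction. No shared effect of the replicate number was seen: across genes the differences between replicates 1 and 2 correlated by -0.05, -0.10 and 0.04 between groups. Whether the samples were paired in the experiment cannot be told from these values. With the replicate block 2377, 2320 and 2808 genes were called. Depth limits the counts of called genes: with every library thinned to the shallowest, 2064, 2059 and 2452 were called, against 2492, 2421 and 2908. The other alternatives run moved no count of called genes by over 1.5 times.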

Other observations

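The tests in this part on oxygen, TRP1, the vacuolar proton pump and untailed RNA were chosen after the data were seen. So were the gene lists behind them, while the tests on depth and abundance were written before their values were seen. The camera p-values of these added lists were adjusted over the added lists alone in each comparison, not together with the lists fixed beforehand. That family is smaller, so these adjusted p-values cannot be set beside those of the fixed lists. Whether the calls with an estimated correlation would hold in a joint adjustment was not tested. Of genes repressed by oxygen, a list prompted by TIR1 and ANB1 and holding both, 11 of 15 were lower and 1 higher in the bud27 deletion, with a median log2 fold change of -1.34 and a camera adjusted p = 4.8e-05 (adjusted p = 0.049 with an estimated correlation). Without the genes already named, 9 of 12 were lower and none higher (median -1.13, camera adjusted p = 0.00021), and the call with an estimated correlation was lost (adjusted p = 0.07). The lower ones included the mitochondrial ADP/ATP carrier AAC3 at -3.67 (SE 0.23) and the low-affinity iron transporter FET4 at -3.65 (SE 0.14). Of genes activated by Hap1, a haem-dependent regulator, 11 of 13 were higher and none lower (median 1.16, camera adjusted p = 3.2e-05, and adjusted p = 0.049 with an estimated correlation), with the cytochrome c gene CYC1 at 1.91 (SE 0.15) and the flavohaemoglobin YHB1 at 1.64 (SE 0.19). Without the genes named by the rule 8 of 10 were higher (camera adjusted p = 0.00022), and again the call with an estimated correlation was lost (adjusted p = 0.07). Both lists share members with fixed lists. Oxidative phosphorylation holds CYC1, COR1, CYC7, CYT1, QCR2 and COX5B. Ergosterol synthesis holds ERG9, HMG1, HMG2, CYB5 and NCP1, and the cell wall list TIR1, TIR2 and TIR3. Most Hap1-activated members are therefore in a fixed list. The oxygen-repressed and Hap1 lists are not separate evidence from those fixed lists. COX5B, at 1.14 (SE 0.13), was the oxygen-repressed gene that rose. After rapamycin 10 of the oxygen-repressed genes were higher and 2 lower (camera adjusted p = 0.0017, and adjusted p = 0.065 with an estimated correlation). Without the named genes 7 of 12 were higher and 2 lower there, and the call was lost (adjusted p = 0.066). CYC1 stood at -1.48 (SE 0.15), and the Hap1 list was split at 5 higher and 5 lower, but at 6 and 2 on the deposited CPM scale, where its median moved from -0.14 to 0.43. The direct test put 14 of the 15 oxygen-repressed genes lower in the deletion than after rapamycin (camera adjusted p = 3.6e-08, and adjusted p = 0.043 with an estimated correlation), and without the named genes 11 of 12 (4.1e-06, and adjusted p = 0.075 with an estimated correlation).

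Genes for subunits and assembly factors of the vacuolar proton pump were divided in the deletion, with 4 higher and 8 lower of 18 (camera adjusted p = 0.10). On the deposited CPM scale 6 were higher and 6 lower. After rapamycin 2 were higher and 6 lower (camera adjusted p = 0.096), but 8 higher and 3 lower on the deposited scale, where the median turned from -0.33 to 0.26. The largest falls in the deletion were VMA11 at -2.98 (SE 0.27), VMA3 at -2.50 (SE 0.16) and VMA16 at -2.16 (SE 0.20), which were lower after rapamycin too, at -1.60, -1.28 and -0.99, and the largest rise was VMA2 at 1.15 (SE 0.21). RNA polymerase III transcripts had 10 of 12 rows lower and none higher in the deletion (median -1.24, camera adjusted p = 0.00015, and adjusted p = 0.078 with an estimated correlation), and 10 lower after rapamycin (median -1.89, camera adjusted p = 8.1e-06, and adjusted p = 0.065 with an estimated correlation). Small nucleolar RNAs had 22 lower and 4 higher of 53 in the deletion (median -0.30, camera adjusted p = 0.023, and adjusted p = 0.22 with an estimated correlation), and 43 lower and 2 higher after rapamycin (median -1.46, camera adjusted p = 6e-13, and adjusted p = 0.055 with an estimated correlation). On the deposited CPM scale the RNA polymerase III medians were -0.90 in the deletion and -1.47 after rapamycin. Those of the small nucleolar RNAs were 0.10, with 11 rows higher and 10 lower, and -0.93. Rows of small nuclear and nucleolar RNAs held 0.156% and 0.178% of the listed reads in WT, 0.202% and 0.155% in the deletion and 0.154% and 0.149% after rapamycin.

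Ribosomal protein, translation factor and glycolysis genes, which are abundant, were lower in the deletion, whose libraries are shallow. The median of their 194 rows was -0.72 with all reads and -0.69 after thinning every library to the shallowest. Thinning keeps the expected CPM of each row, so for abundant rows this median could hardly move. It shows only that the number of reads by itself did not set these values. Other ways in which the shallow deletion libraries may differ were not tested. A general loss of abundant transcripts may explain part of the fall of these genes. Translation factors lay at percentile 4.9 of lists of equal WT abundance, within the range such a trend allows. Glycolysis, at percentile 0.69, had a lower median than its matched lists, -1.40 against -0.90. These percentiles ignore correlation within a list, and the rows drawn may be less abundant than the members they replace. Camera with an estimated correlation did not call glycolysis (adjusted p = 0.30), but it called none of the 30 lists. Ribosomal proteins lay at percentile 100, with -0.56 against -0.91, so they fell less than the rows drawn as nearest in abundance. Whether their fall has a cause beyond that trend cannot be told apart here. An effect of the deletion itself stays open and untested.

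The oxygen-regulated genes and TRP1 prompted 3 explanations: better aeration of the deletion cultures, a background with more Hap1 activity, and a TRP1 allele that differs between the strains, although the labels give BY4741 for all samples. The values behind them were that 91.7% of the 12 oxygen-repressed genes past the threshold were lower, that 100% of the 11 Hap1-activated genes past it were higher, and that the log2 fold change of TRP1 minus the median of TRP2, TRP3, TRP4 and TRP5 was -5.50. The genes behind that median were divided: TRP5 fell, at -0.77 (SE 0.15), while TRP2, TRP3 and TRP4 stood at 1.47 (SE 0.14), 1.49 (SE 0.44) and 2.92 (SE 0.22). Because these values were seen first, they test none of the explanations, which cannot be told apart here from each other or from an effect of losing Bud27. Of genes that BY4741 lacks, chosen after their values were seen, LEU2 had 1 and 14 reads in WT, 19 and 22 in the deletion and 1 and 1 after rapamycin (log2 fold change in the deletion 2.01, SE 0.31, adjusted p = 0.0016), MET17 had 31 and 80, 2 and 3, and 0 and 0 (-1.36, SE 0.40, adjusted p = 0.025), and URA3 had 70 and 42, 10 and 14, and 66 and 42 (-0.14, SE 0.19, adjusted p = 0.58). Where these reads come from was not tested.

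Many RNAs without a poly(A) tail were lower, in libraries primed on poly(A), where their reads depend on capture, but most small nucleolar RNA rows in the deletion were not called as lower. If lower capture of untailed RNA were the source, RNA polymerase III transcripts and small nucleolar RNAs could be expected to fall alike. In the deletion their medians differed by -0.94 (two-sided permutation p = 0.0051 over 100000 resamples of the rows, which are not independent replicates), more than the 0.5 log2 units that would have counted for it and less than the 1 that would have counted against it. After rapamycin they differed by -0.43 (permutation p = 0.13), within the 0.5 that would have counted for it, but the medians of both classes had been seen before that bound was applied. Lower capture and a lower level of these RNAs therefore cannot be told apart in either condition, since the classes could also differ in how they are captured.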
